A study of Escherichia coli K-12 with 4 samples.

How the data were processed

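RNA of Escherichia coli K-12 strain BW25113 was measured on 4 two-colour Agilent arrays of 60-base probes, all on 1 slide. Per the labels, an overnight culture in rich medium was diluted to an OD600 of 0.02 in M9 medium with supplements, grown at 37 °C and 250 rpm to an OD600 of 0.1, and given 5% isooctane. The times sampled were 0, 10, 30 and 60 min. RNA came from 5 ml of each culture, and 10 µg was labelled with Cy3 or Cy5. Each time has 2 biological replicates. In replicate 1 an array held 0 min in Cy5 with 10 min in Cy3 and another held 30 min in Cy5 with 60 min in Cy3, and in replicate 2 the dyes were exchanged.

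The authors scanned the arrays with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. Per the file headers, the mean spot signals and the median local backgrounds are raw intensity values, and the processed signals are intensity values after the software's background subtraction and dye normalization. The deposited value table holds the log10 of the red over the green processed signal, and it equals the log ratio column of the scanner files in all 4 arrays (largest difference 0). Per the file headers, the other columns used hold flags of 0 or 1 for spots well above background, saturated spots and outlier spots.

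Each array had 15744 spots, of which 4250 were control spots. The 11494 others carried 10691 probes, and 4234 of these were for 4209 K-12 genes. The analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0. Mean signals were corrected with the median local background by normexp with an offset of 50 and normalized by loess within each array, with control and outlier spots given no weight. Outlier spots (25 to 38 per channel) were left out and spots of the same probe were averaged. For genes with several probes (24 genes) the brightest probe was used. Probes had to be well above background in both replicates of at least 1 time, which removed 4 genes (araB, araA, rhaB and rhaA), and 2 more lacked values after the outlier spots were left out. This left 4203 genes, 4046 of them named by locus tag from the RefSeq table and 157 under the name in the file. Of the tested probes 31 match several K-12 genes. No spot was saturated.

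Comparisons of times on the same array (10 min against 0 min, 60 min against 30 min) used limma on within-array log2 ratios, with both pairs of arrays in 1 fit that shares the estimate of the spread (2 residual degrees of freedom). The other comparisons (30 min against 0 min, 60 min against 0 min, 30 min against 10 min) and the F test over the 4 times used limma's separate-channel fit after Aquantile normalization between arrays (4 residual degrees of freedom, intraspot correlation −0.0318). Times of different pairs never share an array, so a difference between the arrays cannot be taken out of these comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Lists of genes (51, with 1210 of 1246 genes measured) were tested with camera at the preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. The lists, tests and thresholds were written down before the value files were available.

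Named genes are those called with replicates of the same sign (between arrays: with no overlap of the replicates of both times), the 15 highest and 15 lowest log2 ratios per comparison. Where fewer than 10 genes passed, the 10 highest and 10 lowest at 2-fold or more on both arrays are given as values. Of each described list up to 4 members with the smallest p are named, and marA, soxS, rob, acrA, acrB, tolC, ompF, ompC, pspA, degP and the genes deleted in the strain were chosen in advance.

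The fits were tested on simulated data of 4203 genes with the spread of the real arrays. Of 100 genes changed 2-fold and 100 changed 4-fold, 5% and 79% were called in the design of 10 min against 0 min (2 false of 86 calls), 10% and 83% in that of 60 min against 30 min (6 false of 99), and 34% and 87% in that of 30 min against 0 min (6 false of 127). A 2-fold change was therefore mostly missed, and a gene that was not called may have changed. The rates hold for that many changed genes and for a spread taken from both pairs of arrays together. In the real arrays of 60 min against 30 min, trpE at −3.14 and mtr at −2.84 were not called (limma adjusted p = 0.153 and 0.587). Changes above 4-fold may therefore also be missed there. In simulated lists of genes drawn independently of each other, camera called the shifted list and 0 of 50 unshifted lists at the preset correlation. False calls in lists whose genes vary together were therefore not tested. Camera missed the shifted list with an estimated correlation (adjusted p = 0.946), and 1 simulated list does not measure the power of that setting.

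Alternatives were the processed signals, an offset of 16, median centring, no filter, the mean over probes, all non-control probes, quantile or no normalization between arrays, a replicate block, a dye term, the authors' value table, an adjusted p under 0.1, a 2-fold change without a test, and leaving out each array in turn. The fit of a pair's arrays alone, loess on K-12 spots only and the fit of 0, 30 and 60 min channels only were added after the data were seen. Probes for other E. coli strains were left out of the comparisons, as they do not name a K-12 gene.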

Results

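Transcript levels were measured on two-colour DNA arrays in Escherichia coli K-12 strain BW25113, a laboratory strain described as lacking functional arabinose (araBAD), rhamnose (rhaBAD) and lacZ genes. Cultures growing in a supplemented minimal medium at 37 °C were given 5% v/v isooctane, a branched alkane that barely dissolves in water. RNA was taken at 0, 10, 30 and 60 min, with 2 biological replicates per time. No culture without isooctane was sampled at 10, 30 or 60 min. Effects of the solvent therefore cannot be told apart from those of time in culture or handling. The labels do not say how far the replicates were kept apart before the solvent was added, so p-values measure the spread between these samples only. Each of the 4 arrays carried a pair of times. The 0 and 10 min samples of each replicate shared an array, and so did the 30 and 60 min samples, with the dyes exchanged between replicates. In replicate 1 the median signal of the K-12 spots was 1822 at 0 min, 1224 at 10 min, 2749 at 30 min and 1869 at 60 min, and in replicate 2 it was 1172, 764, 2048 and 1316 at the same times. The local background was 46 to 53, and 99.2% to 99.9% of the K-12 spots were well above background in each channel. The tests covered 4203 genes. The small number of arrays limits the precision of every comparison. Values are log2 ratios of the later over the earlier time, from 2 replicates per time. For times on the same array they are given with the SD of the replicate arrays, and for times on different arrays with the standard error of limma's fit, since nothing but a number pairs those replicates. The words "rose" and "fell" are used for genes with a limma adjusted p under the threshold of 0.05, which was set, with the gene lists and the tests, before the data were examined.

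Ratios are relative to the bulk of the spots on an array. After loess the median K-12 gene lay at −0.14 for 10 min against 0 min and at 0.13 for 30 min against 10 min. Median centring moved this median to −0.50 and 0.43 and put it at −0.33 for 60 min against 30 min and −0.31 for 60 min against 0 min. Without normalization between arrays it was 0.76 for 30 min against 10 min, 0.63 for 30 min against 0 min and 0.66 for 60 min against 0 min. Across genes, which are not independent replicates, the ratios of the replicate arrays correlated at r = 0.679 for 10 min against 0 min and r = 0.655 for 60 min against 30 min. The channels of 30 and 60 min lay closest to each other (r 0.965 to 0.979 across genes). The 10 min channels were farther from those of 0 min (0.789 to 0.888), 30 min (0.829 to 0.845) and 60 min (0.860 to 0.877), whereas the 0 min channels correlated at 0.889 to 0.944 with 30 min and 0.916 to 0.959 with 60 min.

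**Figure D1:**
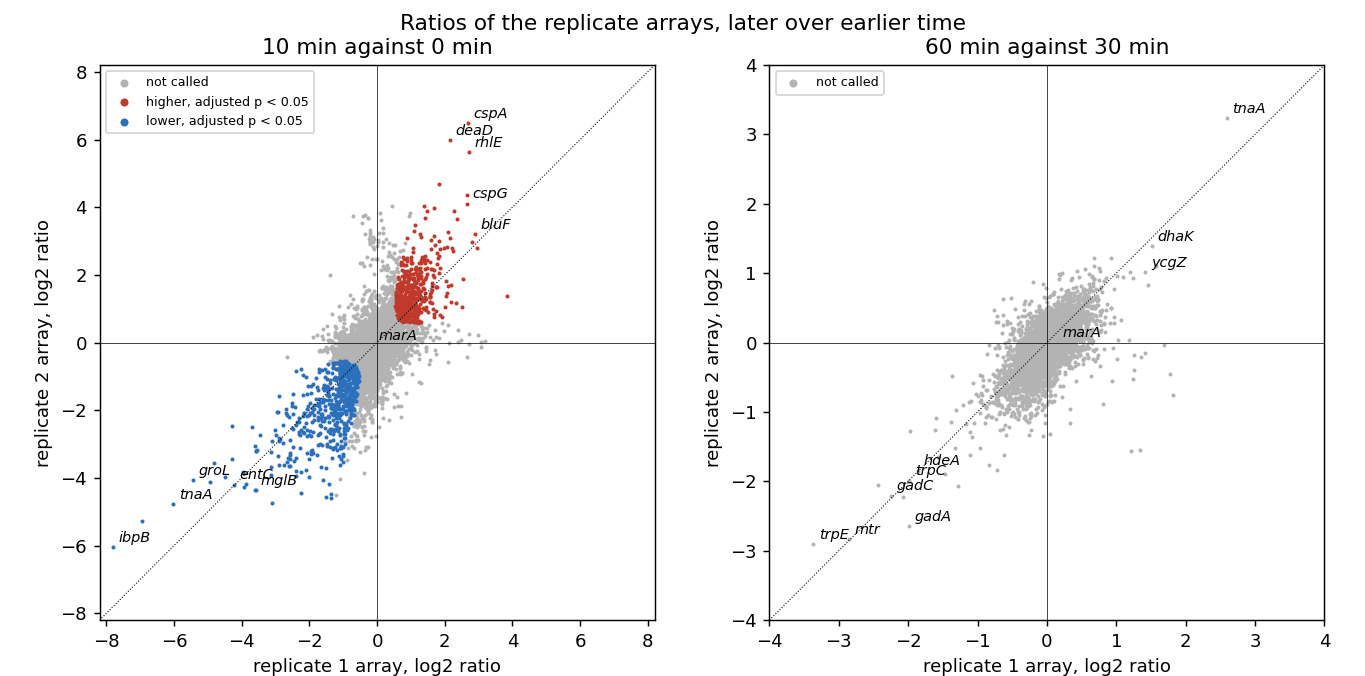
Log2 ratios of 4203 genes on the replicate 1 array (x axis) and the replicate 2 array (y axis), for 10 min against 0 min (left) and 60 min against 30 min (right), with genes called higher in red, lower in blue and not called in grey, and a dotted line of equality. In the left plot ibpB lies at −6.93 on average and cspA at 4.58, and the replicate 2 ratios are wider (SD 1.41 times that of replicate 1).

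The first comparison asked which transcripts differed after 10 min with isooctane from those before it. The chaperone gene groL, the enterobactin gene entC and the galactose transport gene mglB were among the 15 lowest, and the cold shock genes cspA and cspG among the 15 highest. The small heat shock protein genes ibpB (b3686) and ibpA (b3687), whose products bind unfolded proteins, changed most, with log2 ratios of −6.93 ± 1.25 and −6.11 ± 1.18, or 122-fold and 68.9-fold lower. tnaA, which encodes tryptophanase, was 42.2-fold lower (−5.40 ± 0.88). The largest rise was that of cspA (b3556), the major cold shock protein, at 4.58 ± 2.68 (23.9-fold, adjusted p = 0.0242). In all, 1012 of 4203 genes changed in limma's test, 453 upward and 559 downward. These directions rest on the labels: an exchange of the 0 and 10 min samples on both arrays cannot be told apart from a transient response. It would turn every sign here, making ibpB the largest rise, and would swap the comparisons of later times with 0 min and with 10 min.

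Of 24 measured genes under the heat shock sigma factor, 17 fell, none rose and 7 were not called, and 20 fell when p was adjusted over the list alone. The list's shift had a camera adjusted p of 1e-09, and adjusted p = 0.443 with an estimated correlation between genes. The chaperonin genes groL (−4.75 ± 0.98) and groS (−4.53 ± 0.56), the chaperone genes htpG (−4.23 ± 0.38) and dnaK (−4.19 ± 0.91) and the disaggregase gene clpB (−3.85 ± 0.60) were among the 15 lowest of all genes. On the normalized log2 intensity scale, which compares times of 1 probe and not genes, ibpB was at 15.70 ± 0.12 at 0 min and 8.77 ± 1.13 at 10 min (mean ± SD). None of the 28 list shifts called here (13 upward, 15 downward, of 51 lists) was called with an estimated correlation, where the lowest adjusted p was 0.443. With an estimated correlation camera's test has only the fit's 2 residual degrees of freedom. For the heat shock list the estimated correlation was 0.0055, below the preset 0.01. Its camera p before adjustment still went from 5.91e-11 to 0.0206. A missing call in that setting therefore cannot decide whether a list shifted. Other lists differed in this respect. The estimated correlation was 0.976 for ribosomal proteins, 0.704 for RpoS genes and 0.541 for the cold shock list, but −0.0158 for the SOS list. Where the estimate lies far above the preset, the camera p at the preset may be much too small.

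Iron uptake genes made the most uniform group, with 33 of 43 lower, none higher and 10 not called (37 lower adjusted over the list alone; camera adjusted p = 4.05e-14; adjusted p = 0.577 with an estimated correlation). The enterobactin synthesis genes entC (−4.22 ± 0.03) and entE (−4.10 ± 0.25), the iron reductase gene fhuF (−4.02 ± 0.22) and the siderophore receptor gene cirA (−3.98 ± 0.55) led it. Genes of iron-sulfur cluster assembly followed, with 12 of 16 lower, none higher and 4 not called, also 12 lower adjusted over the list alone (camera adjusted p = 6.8e-06; adjusted p = 0.443 with an estimated correlation). sufB reached −2.97 ± 0.73 and iscU −2.15 ± 0.52. Phosphate starvation genes fell in 13 of 19 cases, with none higher and 6 not called (14 lower adjusted over the list alone; camera adjusted p = 2.88e-06; adjusted p = 0.443 with an estimated correlation), and pstS, the phosphate-binding protein gene, stood at −2.41 ± 0.36.

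Among genes of sugar and acetate uptake under catabolite control, 40 of 65 fell, none rose and 25 were not called (47 lower adjusted over the list alone; camera adjusted p = 1.93e-13; adjusted p = 0.443 with an estimated correlation). The galactose transport genes mglB (−3.99 ± 0.53) and mglA (−3.36 ± 0.26) and the acetate permease gene actP (−3.17 ± 0.07) were among its strongest members. Of the genes of the general stress sigma factor RpoS, 22 of 43 fell, none rose and 21 were not called (29 lower adjusted over the list alone; camera adjusted p = 1.67e-08; adjusted p = 0.61 with an estimated correlation). The strongest of them was glaH at −3.90 ± 0.09. Fatty acid degradation genes fell in 9 of 17 cases, none rose and 8 were not called (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000954; adjusted p = 0.557 with an estimated correlation). fadB led them at −3.25 ± 0.51. Of 33 genes of glycolysis and the pentose phosphate pathway, 12 fell and 21 were not called, with 21 lower adjusted over the list alone (camera adjusted p = 2.71e-06; adjusted p = 0.607 with an estimated correlation). gapA, the glyceraldehyde phosphate dehydrogenase gene, was at −2.00 ± 0.09.

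The genes that rose at 10 min included RNA helicases and cold shock proteins. rhlE (4.18 ± 2.05) and deaD (4.07 ± 2.70), both encoding RNA helicases, came directly after cspA, and the cold-inducible cspG, cspB and cspI reached 3.38 ± 1.01, 3.09 ± 1.14 and 2.88 ± 0.10. In the cold shock list 8 of 14 genes rose, 5 were not called and 1 fell, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.9e-05; adjusted p = 0.583 with an estimated correlation). The member that fell was cspD (−2.66 ± 0.84), which is a starvation gene rather than a cold-induced one. The rise was larger in the cold-inducible members but not limited to them. cspF, cspH and cspE, which cold does not induce, also rose (2.42 ± 1.02, 1.93 ± 0.78 and 1.88 ± 0.65). cspC, which cold does not induce either, was not called (1.58 ± 1.34). cspF, cspH and cspC were picked after their values were seen. Outside that list fis, which encodes a nucleoid protein of fast growth, rose 8.02-fold, and bipA, which encodes a ribosome-associated GTPase, by a log2 ratio of 2.69 ± 0.83.

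The lists of ribosomal proteins, lipopolysaccharide synthesis, fatty acid synthesis and the SOS response were also shifted upward at the preset correlation and not with an estimated correlation, with most of their genes not called. The 52 ribosomal protein genes had a median of 1.48, yet only 5 rose and 47 were not called (none adjusted over the list alone; camera adjusted p = 2.41e-09; adjusted p = 0.633 with an estimated correlation). rpsT was at 1.68 ± 0.68. Lipopolysaccharide synthesis genes rose in 13 of 47 cases, 33 were not called and 1 fell (16 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.08e-05; adjusted p = 0.583 with an estimated correlation). The lipid A flippase gene msbA was at 1.88 ± 0.42. Fatty acid synthesis genes rose in 10 of 28 cases, with 1 lower and 17 not called (18 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000119; adjusted p = 0.577 with an estimated correlation). The member that fell was cfa (−2.02 ± 0.90), which encodes the enzyme that modifies finished fatty acids into cyclopropane forms. In the SOS list, the DNA damage response, 9 of 28 genes rose, none fell and 19 were not called (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.88e-05; adjusted p = 0.443 with an estimated correlation). dinG was at 1.71 ± 0.48 and yebG at 1.37 ± 0.05. recA, the activator of that response, was not called at −0.16 ± 0.09 (this gene was picked after its values were seen).

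Few genes tied in the literature to solvent tolerance rose at 10 min. Of all 4203 genes 453 rose and 559 fell, so lists of this size would hold few risen genes in any case. marA (b1531), the regulator gene of multiple antibiotic resistance, was at −0.10 ± 0.02, and the efflux pump genes acrA, acrB and tolC were at −0.07 ± 0.34, 0.08 ± 0.38 and −0.48 ± 0.29, none of them called. The regulator gene soxS fell (−1.86 ± 0.45), as did the phage shock gene pspA (−1.30 ± 0.56), the periplasmic protease gene degP (−1.27 ± 0.76) and the porin gene ompC (−1.43 ± 0.52), and ompF was not called (−0.43 ± 0.15). In the list of genes activated by MarA, SoxS or Rob, 3 of 35 rose, 8 fell and 24 were not called (4 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.346; adjusted p = 0.744 with an estimated correlation). Multidrug efflux genes split into 4 higher, 2 lower and 27 not called of 33 (1 higher adjusted over the list alone; camera adjusted p = 0.0664; adjusted p = 0.686 with an estimated correlation). Highest among those called was mdfA at 1.76 ± 0.39. Among 26 genes reported to alter alkane or solvent tolerance, 1 rose, 9 fell and 16 were not called, and the counts adjusted over the list alone were 1 and 9 (camera adjusted p = 0.0824; adjusted p = 0.577 with an estimated correlation), and the mannose transport genes manY and manX were at −2.26 ± 0.52 and −2.21 ± 0.69. No shift was called for 18 porin genes (3 lower, 15 not called; camera adjusted p = 0.122; adjusted p = 0.583 with an estimated correlation), with the same counts adjusted over the list alone. The 18 genes of the Cpx envelope response gave 2 higher, 4 lower and 12 not called, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.581; adjusted p = 0.903 with an estimated correlation).

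All 30 genes named for the size of their change at 10 min kept their call under each alternative tried. They were picked as the largest called changes on these same arrays, so a lost call was unlikely from the start. The count varied with the arrays and the threshold. This pair's arrays alone gave 663 genes, an adjusted p under 0.1 gave 1589, and 495 genes changed 2-fold on both arrays. Median centring changed the split to 256 higher and 916 lower, and the shift of the ribosomal list was not called without the replicate 2 array of this pair.

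The next comparison, 30 min against 10 min, asked how levels moved between these times. The highest ratios were those of single acid resistance genes. gadB, a glutamate decarboxylase gene, was 54.6-fold higher at 30 min (5.77 ± 0.45), hdeB and hdeA, which encode periplasmic acid chaperones, reached 5.69 ± 0.65 and 5.30 ± 0.69, and the antiporter gene gadC reached 5.00 ± 0.43. The probe of gadB matches 2 K-12 genes, so its signal may hold gadA, which has its own probe at 5.16 ± 0.61. Of the RNA helicase and cold shock genes, those that fell furthest included rhlE at −4.00 ± 0.61, cspG at −3.87 ± 0.39, cspB at −3.57 ± 0.43 and deaD at −3.53 ± 0.80. In limma's separate-channel fit 1864 genes changed, 1136 upward and 728 downward.

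Of the 15 lists lower at 10 min than at 0 min at the preset correlation, 10 were higher at 30 min than at 10 min. With an estimated correlation no list was called in either comparison (lowest adjusted p = 0.443 and 0.223). Both comparisons hold the 10 min channels with opposite sign, so noise in those channels alone gives opposite shifts. In a count added after the data were seen, 459 of the 693 genes lower at 10 min in the separate-channel fit were among the 1136 higher at 30 min. Draws with no effect shared 388 on average over 100 simulations and independent lists would share 187. Iron uptake genes were higher in 31 of 43 cases, none lower and 12 not called (37 higher adjusted over the list alone; camera adjusted p = 1.14e-09; adjusted p = 0.456 with an estimated correlation). fhuF was at 3.32 ± 0.30 and entE at 3.11 ± 0.23. RpoS-dependent genes gave 31 higher, none lower and 12 not called of 43 (33 higher adjusted over the list alone; camera adjusted p = 1.13e-06; adjusted p = 0.683 with an estimated correlation). The catalase gene katE was at 3.19 ± 0.45. Of the sugar and acetate uptake genes, 37 of 65 rose, none fell and 28 were not called, and 37 rose adjusted over the list alone (camera adjusted p = 4.96e-06; adjusted p = 0.375 with an estimated correlation). actP (3.73 ± 0.32) and mglB (3.55 ± 0.24) were among its strongest members. Acid resistance genes rose in 15 of 21 cases, with none lower and 6 not called (16 higher adjusted over the list alone; camera adjusted p = 6.44e-06; adjusted p = 0.375 with an estimated correlation). Heat shock genes rose in 12 of 24 cases with 12 not called, and 12 rose adjusted over the list alone (camera adjusted p = 0.0293; adjusted p = 0.742 with an estimated correlation). groL was at 3.05 ± 0.58, although ibpB, at a level (mean ± SD) of 10.66 ± 0.72 at 30 min, stayed below its 0 min level. The shift of the heat shock list was not called with median centring, quantile normalization or no normalization between arrays. Cysteine and sulfur assimilation genes gave 18 higher, 2 lower and 10 not called of 30 (20 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00554; adjusted p = 0.71 with an estimated correlation). Its member cysK was at 3.01 ± 0.42.

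Of the 13 lists higher at 10 min than at 0 min, 11 were lower at 30 min than at 10 min, again at the preset correlation only and with the same limit. Of the 544 genes higher at 10 min 420 were among the 728 lower at 30 min, where draws with no effect shared 239 and independent lists would share 94.2. In the cold shock list 7 of 14 genes fell, 1 rose and 6 were not called, with the same counts of 7 and 1 adjusted over the list alone (camera adjusted p = 0.00142; adjusted p = 0.564 with an estimated correlation). SOS genes were lower in 14 of 28 cases, none higher and 14 not called (17 lower adjusted over the list alone; camera adjusted p = 4.44e-06; adjusted p = 0.223 with an estimated correlation). dinG was at −2.99 ± 0.21. Lipopolysaccharide synthesis genes fell in 21 of 47 cases, with 2 higher and 24 not called, and 21 and 2 adjusted over the list alone (camera adjusted p = 6.44e-06; adjusted p = 0.435 with an estimated correlation). The sugar transferase gene waaO was at −2.00 ± 0.21. Genes of fatty acid synthesis gave 10 lower, 2 higher and 16 not called of 28, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.000331; adjusted p = 0.435 with an estimated correlation), and pgpB was at −2.07 ± 0.19. ftnA, the iron storage protein gene, fell by 3.08 ± 0.30. These times never shared an array. In a fit without 1 array the spread came only from the pair left complete, so its count does not show which arrays the calls rested on. Median centring gave 1616 higher and 450 lower, no normalization between arrays 1382 and 76, a dye term 1209 genes in all, and all probes of the array 3347.

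**Figure D2:**
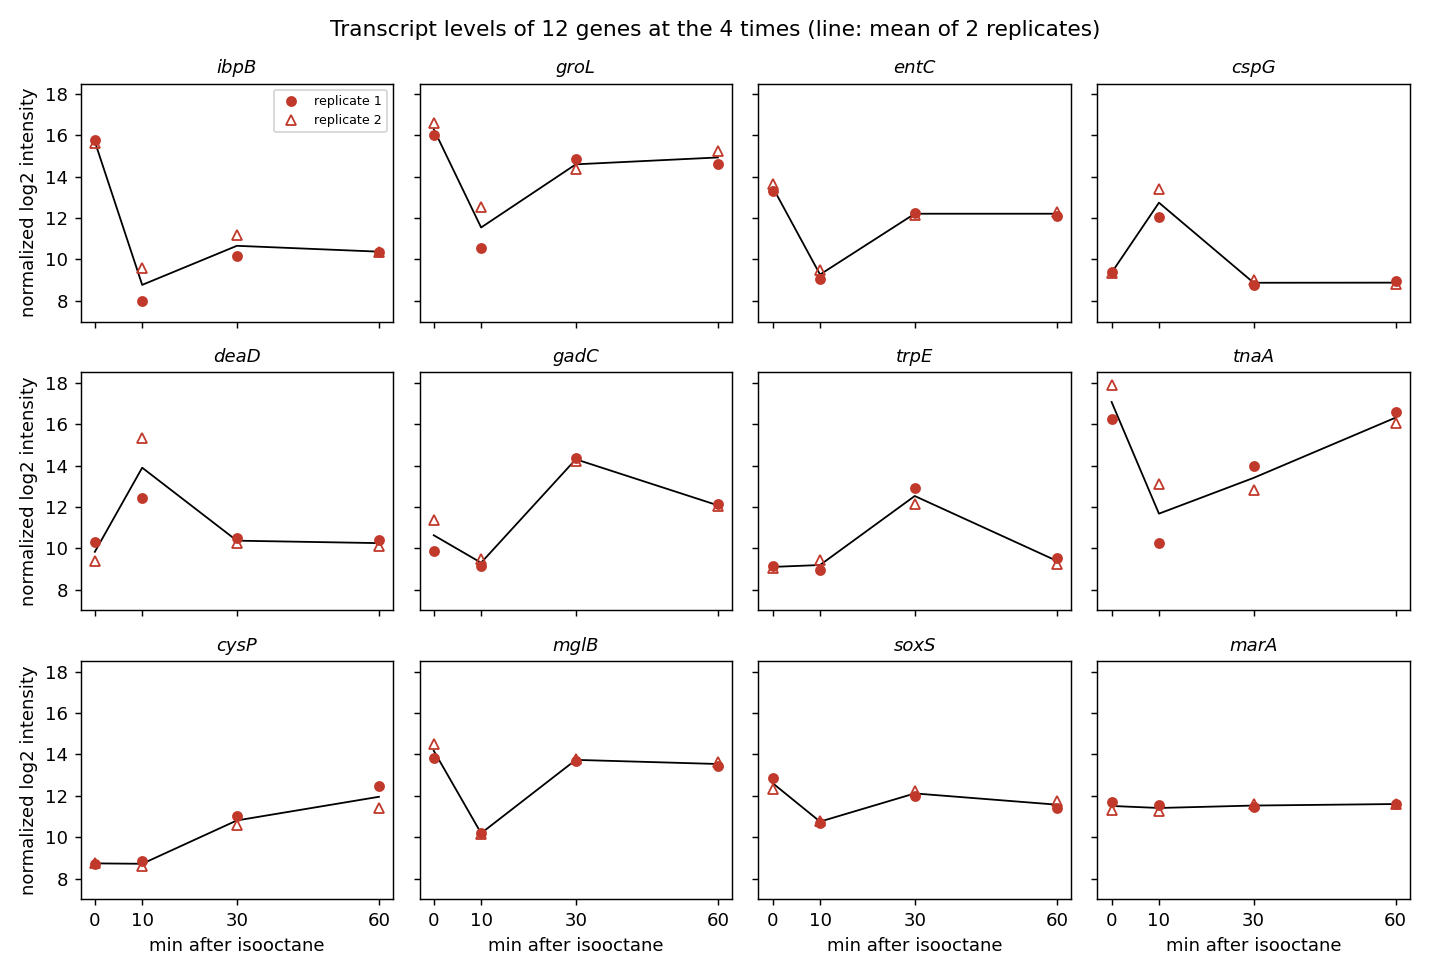
Normalized log2 intensity (y axis) of 12 genes at 0, 10, 30 and 60 min after isooctane (x axis, min), with circles and triangles for replicates 1 and 2 and a line through their mean. ibpB drops from 15.70 to 8.77 by 10 min, cspG is highest at 10 min (12.75), gadC and trpE are highest at 30 min (14.30 and 12.53), and marA stays between 11.41 and 11.60.

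The 30 min samples were then compared with those of 0 min. gadB and gadC were 12.9-fold and 12.8-fold higher (3.69 ± 0.45 and 3.67 ± 0.43). The tryptophan permease gene mtr and the tryptophan synthesis gene trpE (b1264) were 11.9-fold and 10.8-fold higher (3.57 ± 0.41 and 3.43 ± 0.29). The thiosulfate uptake gene tsuA rose by 3.15 ± 0.30 and the sulfate permease gene cysW by 2.95 ± 0.48. Lowest were ibpB, 32.8-fold lower (−5.04 ± 0.51), and ibpA, 29.4-fold lower (−4.88 ± 0.38). In limma's separate-channel fit 118 genes changed, 52 upward and 66 downward.

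The acid resistance list gave 8 higher, none lower and 13 not called of 21, and 14 higher adjusted over the list alone (camera adjusted p = 1.93e-07; adjusted p = 0.586 with an estimated correlation). Its regulator gene gadE was at 2.17 ± 0.34, and mdtE, which encodes part of an efflux pump and sits in both this list and the efflux list, was at 2.01 ± 0.24. Of 30 cysteine and sulfur genes 4 rose and 26 were not called, with 14 higher adjusted over the list alone (camera adjusted p = 6.21e-05; adjusted p = 0.773 with an estimated correlation). The cystine transporter gene tcyP was at 2.63 ± 0.45 and cysP at 2.08 ± 0.35. Heat shock genes fell in 7 of 24 cases, none rose and 17 were not called, while 19 fell adjusted over the list alone (camera adjusted p = 9.2e-11; adjusted p = 0.586 with an estimated correlation). htpG was at −2.14 ± 0.34 and the protease gene lon at −1.92 ± 0.35. Of the aromatic amino acid genes 5 of 23 rose, none fell and 18 were not called, with 5 higher and 3 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.125; adjusted p = 0.647 with an estimated correlation). trpB and trpA of the trpE operon were not called. The phosphate starvation list was not called either (camera adjusted p = 0.0984; adjusted p = 0.773 with an estimated correlation), with 4 of 19 lower and 15 not called, and 2 higher and 7 lower adjusted over the list alone. Of single genes, phoH and pstS of that list were at −2.59 ± 0.34 and −2.47 ± 0.23, the biofilm regulator gene bssS at −2.49 ± 0.24, and the neighbouring small genes ycgZ, ymgA, ariR and ymgC between −2.31 ± 0.29 and −2.13 ± 0.22. Iron uptake genes gave 2 lower and 41 not called of 43, with 9 lower adjusted over the list alone (camera adjusted p = 0.000524; adjusted p = 0.773 with an estimated correlation), and entC was at −1.28 ± 0.22. marA (0.02 ± 0.21), acrB (−0.40 ± 0.25) and soxS (−0.49 ± 0.24) were not called, and pspA fell (−1.78 ± 0.34).

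Multidrug efflux genes were shifted upward with a median of 0.34, with 2 of 33 higher, 31 not called and 3 higher adjusted over the list alone (camera adjusted p = 0.00705; adjusted p = 0.773 with an estimated correlation). The called members were mdtE and mdtF (1.13 ± 0.21), and the shift was not called without the replicate 2 array of 0 and 10 min. Genes activated by MarA, SoxS or Rob were shifted downward with a median of −0.33, with none of 35 called, also adjusted over the list alone (camera adjusted p = 0.00705; adjusted p = 0.647 with an estimated correlation). The alkane and solvent tolerance list was lower, with 1 of 26 higher, 1 lower and 24 not called, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.0438; adjusted p = 0.586 with an estimated correlation). That shift was not called with processed signals, an offset of 16, all probes or quantile normalization, nor without the replicate 1 array of either pair.

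The count at 30 min moved widely. Leaving out either array of 30 and 60 min left 0 genes in limma's separate-channel fit (327 without replicate 1 and 406 without replicate 2 at an unadjusted p under 0.05), leaving out the 0 and 10 min array of replicate 1 or 2 gave 1777 and 422, and a dye term gave 13, with the call of gadB, gadC, mtr and ibpB lost and that of trpE, tsuA and ibpA kept. The split was 139 higher and 106 lower with quantile normalization and 566 and 26 with no normalization between arrays.

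After 60 min, tsuA (b2013) was 13.5-fold higher than at 0 min (3.76 ± 0.30), and cysW, cysP and cysU, all of the sulfate and thiosulfate permease, were higher by 3.38 ± 0.48, 3.22 ± 0.35 and 3.14 ± 0.33. ibpB and ibpA remained lowest, 39.9-fold and 35.3-fold below 0 min (−5.32 ± 0.51 and −5.14 ± 0.38). In this comparison limma called 24 genes, 7 upward and 17 downward.

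The 7 genes that rose were tsuA, cysW, cysP, cysU, tcyP, tsuB and appC, of which 6 act in sulfur uptake and appC encodes an oxidase subunit. In the sulfur list 3 of 30 rose and 27 were not called, with 9 higher adjusted over the list alone (camera adjusted p = 3.15e-09; adjusted p = 0.505 with an estimated correlation). Heat shock genes gave 3 lower and 21 not called of 24, with 16 lower adjusted over the list alone (camera adjusted p = 4.36e-13; adjusted p = 0.505 with an estimated correlation), the called ones being ibpA, ibpB and hslR (−1.29 ± 0.18). Phosphate starvation genes gave 3 lower and 16 not called of 19, with 6 lower adjusted over the list alone (camera adjusted p = 0.00916; adjusted p = 0.505 with an estimated correlation), namely phoH (−2.77 ± 0.34), pstS (−2.44 ± 0.23) and phoU (−1.53 ± 0.20). The fatty acid oxidation gene fadB was at −1.83 ± 0.22. Nitrogen assimilation genes were lower as a list with no gene called of 28 and 7 lower adjusted over the list alone (camera adjusted p = 8.46e-07; adjusted p = 0.505 with an estimated correlation). The glutamine synthetase gene glnA was at −2.10 ± 0.45 and not called. Multidrug efflux genes were higher as a list (median 0.35) with none of 33 called, also adjusted over the list alone (camera adjusted p = 0.000193; adjusted p = 0.505 with an estimated correlation). Phage shock genes were lower as a list with none of 7 called and 2 lower adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.505 with an estimated correlation). The phage shock shift was not called without either array of 0 and 10 min or without normalization between arrays. A dye term or the loss of the replicate 1 array of 30 and 60 min ended every call at 60 min (0 genes in limma's separate-channel fit, with 438 and 155 at an unadjusted p under 0.05), and without the replicate 2 array 3 were left, while leaving out the 0 and 10 min array of replicate 1 or 2 gave 1086 and 257. Median centring gave 7 higher and 84 lower, and no normalization between arrays 12 and 2.

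Between 30 and 60 min the largest differences lay in tryptophan and acid resistance genes. The tryptophan synthesis genes trpE, trpD and trpC were at −3.14 ± 0.33, −2.25 ± 0.27 and −1.99 ± 0.01 and the permease gene mtr at −2.84 ± 0.01, while tnaA, which encodes the enzyme that breaks tryptophan down, was at 2.91 ± 0.45. gadA, gadC and gadB were at −2.32 ± 0.47, −2.23 ± 0.03 and −2.15 ± 0.11. No gene passed the threshold in limma's planned fit of all 4 arrays, where the lowest adjusted p was that of trpE (0.153), so these values carry no call there. With a dye term the same arrays gave 8 genes, trpE, trpD, trpC, mtr, tnaA, gadA, gadB and gadC. The count of 0 stood beside 194 genes at an unadjusted p under 0.05 and 26 genes that differed 2-fold on both arrays, 5 higher and 21 lower.

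Of 21 acid resistance genes none was called and 3 were lower adjusted over the list alone (camera adjusted p = 6.2e-08; adjusted p = 0.633 with an estimated correlation). hdeA was at −1.85 ± 0.00 and hdeB at −1.67 ± 0.56. Aromatic amino acid genes gave 6 lower and 1 higher of 23 adjusted over the list alone, none over all genes (camera adjusted p = 0.0108; adjusted p = 0.633 with an estimated correlation). The histidine synthesis list had a median of −0.50, with 3 of 8 lower adjusted over the list alone and hisG at −0.71 ± 0.07 (camera adjusted p = 6.61e-06; adjusted p = 0.633 with an estimated correlation). Branched-chain amino acid genes had a median of −0.43 with none of 21 called, also adjusted over the list alone (camera adjusted p = 4.55e-07; adjusted p = 0.633 with an estimated correlation). The shifts of the aromatic and histidine lists were not called with median centring. Genes activated by MarA, SoxS or Rob were higher as a list (median 0.12) with none of 35 called, also adjusted over the list alone (camera adjusted p = 0.00376; adjusted p = 0.633 with an estimated correlation). Of the genes 2-fold apart on both arrays, all 5 higher ones are named, but only the 10 lowest of the 21 lower ones. The rest of those named were the dihydroxyacetone kinase genes dhaK (1.45 ± 0.09) and dhaL (1.34 ± 0.34), ycgZ (1.22 ± 0.29) and ymgA (1.11 ± 0.12) upward and the pyrimidine gene pyrI (−1.68 ± 0.31) downward. Heat shock genes had a median of 0.06 between these times, with none of 24 called, also adjusted over the list alone (camera adjusted p = 0.249; adjusted p = 0.771 with an estimated correlation). The count varied with the arrays in the fit: limma on the 30 and 60 min arrays alone, with 1 residual degree of freedom and chosen after seeing the data, gave 720 genes (277 higher and 443 lower), among them all 15 genes named for their size, leaving out either 0 and 10 min array also gave 720, and the separate-channel fit gave 3, trpE, trpD and trpC, and all probes of the array 7. The authors' value table gave 0 in the same fit.

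**Figure D3:**
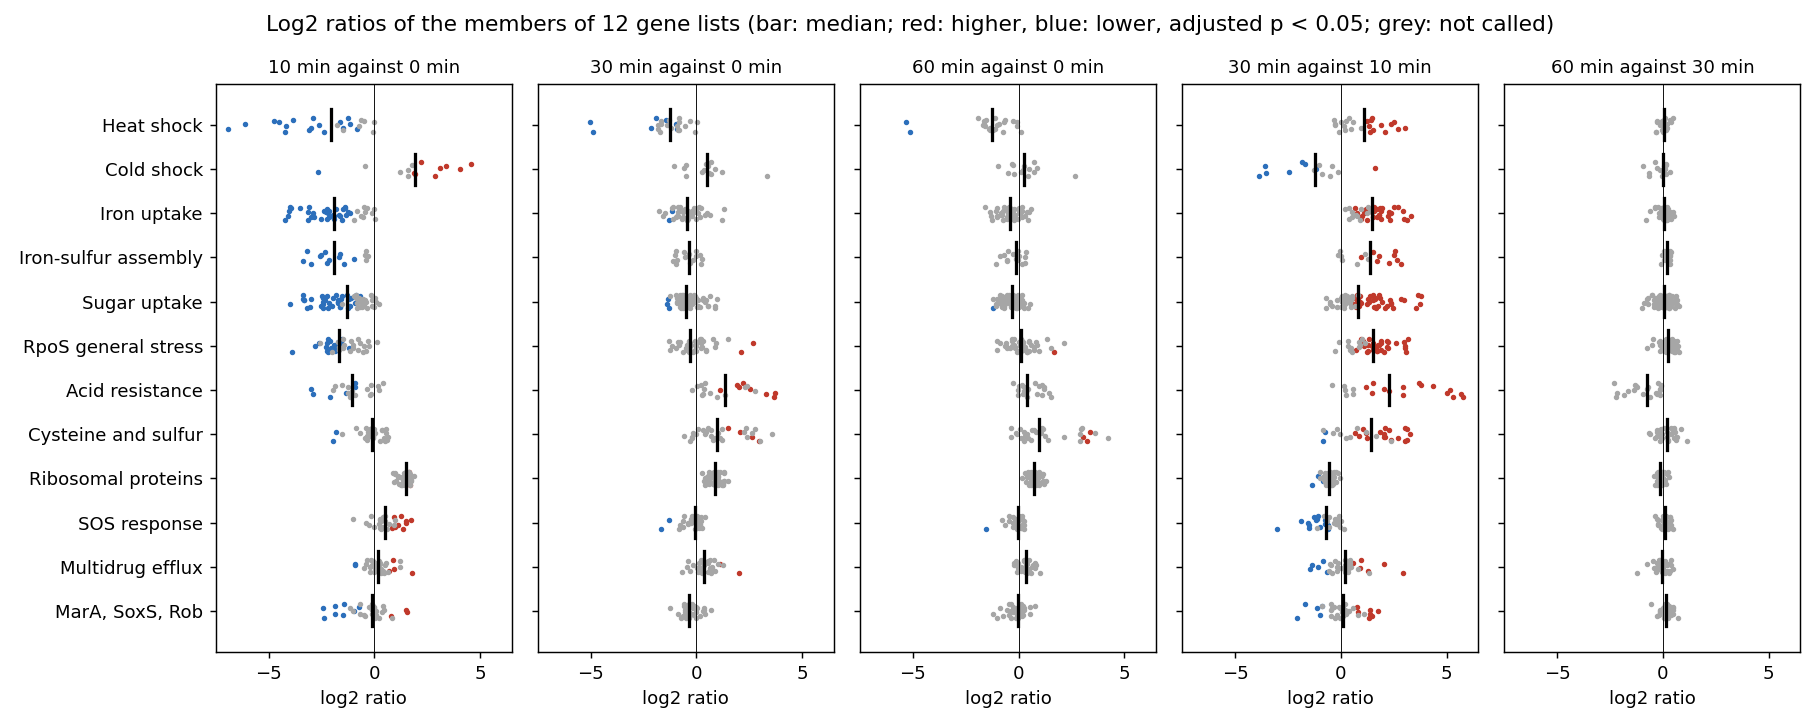
Log2 ratios (x axis) of the measured members of 12 gene lists (y axis) in the 5 comparisons, each point a gene, red where higher, blue where lower and grey where not called, with a bar at the list's median. The heat shock bar lies at −2.07 for 10 min against 0 min and at −1.26 for both later times against 0 min, the cold shock bar moves from 1.90 to 0.49 and 0.23, and the ribosomal bar at 30 and 60 min changes its side of the other genes when arrays are not normalized against each other.

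Over the whole time course 1601 genes changed in limma's moderated F test, which was 14 or 16 genes when the replicate 1 or the replicate 2 array of 30 and 60 min was left out and 3056 without the replicate 1 array of 0 and 10 min. In the separate-channel fit 14 genes were lower than at 0 min at all of 10, 30 and 60 min, and 0 were higher at all of them. Draws with no effect against the same 0 min channels shared 3.21 and 1.25 on average over 100 simulations, and independent lists would share 0.0440 and 0.0112. Of the 66 genes lower at 30 min, 40 were also lower at 10 min, where unchanged groups set against the same 0 min channels shared 41.0 on average over 100 simulations and independent lists would share 10.9. Of the 52 genes higher at 30 min, 2 were also higher at 10 min (29.6 in simulations, 6.73 for independent lists). All 7 genes higher at 60 min were higher at 30 min (1.52 in simulations, 0.0866 for independent lists), and 16 of the 17 genes lower at 60 min were lower at 30 min (3.55 and 0.267). The 0 min channels were too few to split, so part of any excess may come from the shared 0 min channels. The 14 shared genes became 0 without either array of 30 and 60 min and with a dye term, 445 and 64 without the replicate 1 or replicate 2 array of 0 and 10 min, 29 at an adjusted p under 0.1 and 2 without normalization between arrays.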

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

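Apart from the correlation of the replicate arrays, which was planned as a check of the dye labels, the tests in this part were chosen only after the result was seen. A signal in data outside the comparisons drew attention to 2665 of 6457 probes designed for other E. coli strains, which were above background in all 8 channels. The same applied to 3 of the 7 genes listed as deleted in the strain, araD, rhaD and lacZ, whose probes were above background in all 8 channels, while those of araB, araA, rhaB and rhaA were below it in all. No genome was given, so whether the deletions leave part of araD, rhaD and lacZ that the probes match was not checked.

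The cold shock gene cspA was higher and the heat shock gene ibpB lower at 10 min than at 0 min. Wrong dye labels on 1 of the arrays are excluded, since the ratios turned by their labels correlated at r = 0.679 across genes. An exchange of the 0 and 10 min samples on both arrays cannot be told apart from a transient response: the lowest correlation of 0 with 30 min channels lay 0.0439 above the highest of 10 with 30 min channels (0.889 and 0.845), which either would give. A response like that to cold cannot be told apart from other causes, as 9 cold-induced genes outside the fixed list had a median log2 ratio of 0.18, at percentile 70.3 of 10000 random lists of the same brightness (5% to 95%: −0.84 to 0.78). Fresh 0 and 10 min samples would test the exchange, and a 10 min control without isooctane would separate the solvent from time and handling. Neither would show whether the response is like that to cold.

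The ratios of 10 min against 0 min were wider on the replicate 2 array than on the replicate 1 array. Compression of ratios in dim spots is excluded, since the SD of replicate 2 was 1.59 times that of replicate 1 in the brightest of 3 equal groups of genes, 1.38 times in the middle group and 0.922 times in the dimmest. The particular background correction and loess used here are not needed for it, since the authors' value table gave 1.38. That table also went through background subtraction and dye normalization, so it cannot exclude steps of that kind. A larger response in the culture of replicate 2 was not tested and remains open.

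TrpR-regulated genes were lower at 60 min than at 30 min. No gene was called in the main fit of within-array ratios, while the separate-channel fit called trpE, trpD and trpC. All 9 genes were below 0 on both dye-swapped arrays (median log2 ratio −0.97), where a dye effect alone would give opposite signs. trpE, trpD, trpC and mtr cannot test this, as they were named by a rule that asks for the same sign. The genes not named by it, trpB, trpA, aroH, aroL and trpR, argue against a dye effect, though trpB and trpA share the operon of trpE. The 87 genes of the other amino acid lists had a median of −0.27, nearer to no change. The TrpR-regulated set holds trpE, trpD, trpC and mtr, which were picked for their size. The medians therefore cannot exclude a wider fall of amino acid biosynthesis genes. Stronger TrpR repression cannot be told apart from other causes: the targets outside the trp operon and not named for their size, aroH, aroL and trpR, had a median of −0.53, at percentile 10.6 of 10000 random lists of 3 genes of the other amino acid lists (5% to 95%: −0.61 to 0.21). A strain without trpR, sampled at both times, would test it.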

How the results depend on the processing

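The 2-fold threshold without a test was not applied to gene lists, so that alternative was not run there. With 2 replicates per time, 3 arrays leave a lone array that is assumed to vary like the other pair, and where the intraspot correlation could not be estimated (without 60 min against 30 min replicate 1, without 10 min against 0 min replicate 2) the value from all 4 arrays was used. Across the settings that leave out 1 array, counts ranged from 663 to 2355 at 10 min against 0 min, 0 to 720 at 60 min against 30 min, 0 to 1777 at 30 min against 0 min, 0 to 1086 at 60 min against 0 min, 0 to 2486 at 30 min against 10 min, 14 to 3056 over the 4 times and 0 to 445 for genes lower at all of 10, 30 and 60 min. List shifts called ranged from 20 to 29, 12 to 20, 13 to 24, 11 to 26 and 23 to 25 in the same order of comparisons. In these fits the spread came only from the pair left complete, so the gene counts depend on which pair that was. Why the list shifts varied was not tested.

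At 10 min against 0 min (1012 genes) an adjusted p under 0.1 gave 1589, its arrays alone 663 and 2-fold on both arrays 495. At 60 min against 30 min (0 genes) all non-control probes gave 7, the separate-channel fit 3 (trpE, trpD and trpC, adjusted p = 0.0318, 0.0391 and 0.0391), its arrays alone 720 and 2-fold on both arrays 26. At 30 min against 0 min (118) processed signals gave 68, median centring 49, all non-control probes 362, an adjusted p under 0.1 457, quantile normalization 245, no normalization between arrays 592, a dye term 13 and 0, 30 and 60 min channels only 217. At 60 min against 0 min (24) median centring gave 91, an adjusted p under 0.1 46, no normalization between arrays 14, a dye term 0 and 0, 30 and 60 min channels only 50. At 30 min against 10 min (1864) all non-control probes gave 3347 and a dye term 1209, and over the 4 times (1601) all non-control probes gave 2819. The 14 genes lower at all times became 29 at an adjusted p under 0.1, 2 without normalization between arrays and 0 with a dye term. The settings added after the data were seen are the arrays alone, loess on K-12 spots, the 0, 30 and 60 min channels and those of the shared genes. More probes or a looser threshold explain their own counts. A pair's arrays alone have the same log2 ratios as the main fit, so their counts differ through the estimate of the spread. For mtr the SD of the replicate arrays was 0.01 at 60 min against 30 min and 1.46 at 10 min against 0 min. Its standard error in the main fit was 0.487 in both. For the other settings the cause was not tested.

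The labels mark no batch shared by the samples of a replicate number. With 2 pairs only, the deviations correlated at r = 0.169 across genes, and the replicates share only a number. As a block, which in the ratios of 60 min against 30 min is the same term as the dye and cannot be separated from it, it gave 8 genes there (trpE, tnaA, trpD, mtr, gadC, trpC, gadB and gadA), 17 at 30 min against 0 min, 7 at 60 min against 0 min, 1178 at 30 min against 10 min and 3 lower at all times.

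No list was called with an estimated correlation (0 in each of the 5 comparisons). That setting tests on the 2 or 4 residual degrees of freedom of the fits, so a missing call there cannot decide whether a list shifted. A call at the preset cannot decide it either for lists whose genes vary together by far more than the preset. Median centring turned the balance of list shifts: 31 at 60 min against 30 min, 24 higher and 7 lower (18, 8 and 10 with loess), and 29 at 60 min against 0 min, 21 and 8 (16, 5 and 11). No normalization between arrays gave 30 at 30 min against 0 min, 6 higher and 24 lower (16, 7 and 9), and 28 at 60 min against 0 min, 7 and 21, and an adjusted p under 0.1 gave 25 at 30 min against 0 min. With median centring the replicate arrays correlated at 0.627 and 0.609 across genes. These list shifts reversed, with camera p before adjustment: the tricarboxylic acid cycle at 60 min against 30 min (0.0201) and lysine, threonine and serine synthesis at 60 min against 0 min (0.932) with median centring, glycolysis at 30 min against 10 min (0.852) and ribosomal proteins at 30 and 60 min against 0 min (0.845 and 0.563) without normalization between arrays, and, without 10 min against 0 min replicate 2, ribosomal proteins (0.862 and 0.173) and the OxyR regulon at 30 min against 0 min (0.868). Without 10 min against 0 min replicate 1 the last of these gave 4.4e-05 and ribosomal proteins 3.24e-24 and 5.33e-31. At 30 min against 10 min rob reversed to 1.12 without 10 min against 0 min replicate 1 (lowest −1.19, without replicate 2) and ydjM to 0.10 without normalization between arrays. The cause was not tested.

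The counts of list shifts given next leave out the estimated correlation, under which no list kept its call. Of the list shifts at 10 min against 0 min, 328 of 336 values under the remaining settings stayed on their side of the threshold. So did 172 of 192 at 30 min against 0 min and 179 of 192 at 60 min against 0 min. At 30 min against 10 min 253 of 264 did, and at 60 min against 30 min 204 of 216. With 1 array left out these were 99 of 112, 49 of 64, 52 of 64, 88 of 96 and 59 of 72. Named genes kept direction and call in 1736 of 1794, 971 of 1116, 937 of 1044, 1317 of 1375 and 1069 of 1170 values under other settings, and in 517 of 552, 234 of 372, 211 of 348, 271 of 500 and 234 of 360 with 1 array left out. Among the rest, genes that were not called, such as acrA and acrB at 10 min against 0 min, also changed sign. Signals over a local background of 46 to 53 limit only dim probes, as 99.2% or more of the K-12 spots were above background.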

Other observations

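Further gene groups differed between 10 and 0 min. Purine synthesis genes rose in 6 of 17 cases, with none lower and 11 not called (8 higher adjusted over the list alone; camera adjusted p = 9.92e-05; adjusted p = 0.61 with an estimated correlation), with purE at 1.59 ± 0.31 and purK at 1.51 ± 0.31. Genes of the envelope stress sigma factor rose in 7 of 27 cases, with 1 lower and 19 not called, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.000154; adjusted p = 0.443 with an estimated correlation). rseC was at 1.41 ± 0.16 and lpxD at 1.30 ± 0.30, while the protease gene degP was lower. In the OxyR list 10 of 21 fell and 11 were not called, with 13 lower adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.642 with an estimated correlation). Its strongest members, fhuF, sufB, sufA and sufC (−2.54 ± 0.90), also belong to iron uptake or iron-sulfur assembly. Among genes of the SoxRS response 5 of 13 fell and 8 were not called, with 8 lower adjusted over the list alone (camera adjusted p = 0.00544; adjusted p = 0.577 with an estimated correlation), including the superoxide dismutase gene sodA at −2.41 ± 0.37 and fumC at −2.36 ± 0.57. The SoxRS shift was not called with median centring.

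Between 10 and 30 min purine synthesis genes fell in 6 of 17 cases with 11 not called, and 5 fell adjusted over the list alone (camera adjusted p = 0.00239; adjusted p = 0.683 with an estimated correlation), with purE at −1.22 ± 0.29. soxS rose (1.36 ± 0.24), and so did degP (1.69 ± 0.25). The porin gene nmpC, which fell at 10 min (−2.86 ± 0.19), rose by 2.87 ± 0.22, and the outer membrane protease gene ompT went from −3.10 ± 0.60 to a rise of 2.46 ± 0.32. The malate oxidase gene mqo did the opposite, at 2.44 ± 0.54 and then −1.97 ± 0.23. Both comparisons hold the 10 min channels, so noise in them alone gives opposite values.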
